A study of Mus musculus with 10 samples.

How the data were processed

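RNA was sequenced from 10 libraries of F4/80+ macrophages sorted by flow cytometry from melanomas that had regrown under daily BRAF and MEK inhibitors, per the labels' protocols. The libraries came from male mice of 2 genotypes, 5 heterozygous for an RFP allele of Ccr2, called control here, and 5 homozygous for it, called Ccr2 knockout. The titles call the first group wild type while the genotype label calls it Control (Ccr2RFP/+), and the genotype label was followed. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples, which may in part be technical. Polyadenylated RNA was enriched and turned into directional libraries, per the labels' protocols. Reads were aligned with STAR to GRCm39, per the submitters' processing notes, and the STAR version and gene annotation are not given in the sources used here.

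The deposited values were whole-number read counts per gene as STAR writes them, with an unstranded column and a column for each strand. The column for the reverse strand was used, because between 96.2% and 96.5% of strand-assigned counts fell in it in every library. Rows for unmapped, multimapping, ambiguous and unassigned reads were kept out of library sizes and tests. Multimapping reads were listed as 0 in all libraries. Reads shared by near-identical genes were therefore not seen in these counts, and levels of paralogs such as the Ly6 family, Chil3 and the MHC genes are uncertain. On average 7.63% of reads in control and 7.45% in Ccr2 knockout libraries were unmapped, and 1.99% and 2.02% were ambiguous. A further 4.63% and 4.44% met no gene on the strand counted, which can include reads opposite to a gene. Counts per library summed to between 34639808 and 43360206. Of 55359 gene identifiers, 52083 matched a symbol in a table of gene names, and the 3276 that did not held 0.145% of counts. Biotypes and the order of genes came from GENCODE release 21 on GRCm38, so no coordinates are given. A combined count table of the series was not used, because its 10 columns carry no names to match to samples, and a deposited table listing genotypes was not used either.

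Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F-test after filterByExpr with its minimum count of 10 and TMM normalization, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The standard error of a log2 fold change was taken as its size divided by the square root of F. Levels are given as CPM, as edgeR computes it with TMM-scaled library sizes, and as mean ± SD over 5 libraries. Gene lists were tested on log2 CPM with a prior count of 2 by camera in limma 3.58.1 with a preset correlation of 0.01, beside camera with an estimated correlation and fry. Before the data were examined, 47 lists were fixed, 29 of pathways and cell states and 18 of other cell types and technical signs, and each family was adjusted separately. A list needed at least 5 tested genes, which left out Y-linked genes, Xist, skeletal muscle, adipocyte and erythroid markers. In those 5 lists no gene passed the threshold, and the median log2 fold changes were -0.21, -0.45, 0.13, -0.08 and -0.09. A list score was the mean log2 CPM of its tested members, and scores, Ccr2 and library measures were compared by exact two-sided permutation tests over 252 arrangements, whose smallest p is 0.00794.

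The genes named were chosen by a rule fixed beforehand. It took Ccr2, then in each direction the 12 genes with the largest log2 fold change among those past the threshold with a mean of at least 2 CPM and no predicted-gene or pseudogene name, and for each list described up to 4 members with the smallest p in the direction described, with any member at issue in a count of 5 or fewer. Il2rb, S100a9, Col3a1, Wdfy4, Xist, Ddx3y and Uty fall outside this rule and were chosen after their values were seen. Some genes the rule would name are not reported here. Alternatives were DESeq2 size factors, no composition factor, DESeq2 1.42.0, limma-voom with sample quality weights, no filter on low counts, at least 1 CPM in 5 libraries, unstranded counts, the title number as a block, robust dispersions, each library left out in turn, and other thresholds and set tests. The gene test was tested on simulated counts for this comparison, 5 times with about 14168.8 genes passing the filter. It recovered 12.7% of genes changed 1.5-fold, 52.6% of those changed 2-fold and 83.0% of those changed 4-fold, and 4.29% of its calls were false. In the same simulations camera, camera with an estimated correlation and fry each called the planted list of 20 genes in 5 of 5 runs and called 0 of the 29 other lists. Each gene was drawn independently, with no structure shared between libraries. These simulated rates of false genes and lists therefore do not cover correlated genes or libraries that resemble each other. Figures were drawn with matplotlib 3.10.9.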

Results

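Macrophages carrying the surface marker F4/80 were profiled by bulk RNA-seq from Braf-mutant melanomas that had become resistant to BRAF and MEK inhibitors. The tumours grew in control mice, which keep a working Ccr2 allele beside an RFP allele, and in Ccr2 knockout mice, which carry the RFP allele on both chromosomes. Ccr2 is the chemokine receptor through which inflammatory monocytes leave the bone marrow and enter tissue. The 10 libraries, 5 per genotype, held between 34639808 and 43360206 counts in genes. The comparison asks how the macrophage transcriptome of resistant tumours differs when Ccr2 is missing.

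Ccr2 itself (ENSMUSG00000049103) separated the genotypes in every library. It stood at 119 ± 45.9 CPM in control macrophages and 4.72 ± 1.41 CPM in Ccr2 knockout macrophages (SD, n = 5 each), a log2 fold change of -4.66 with a standard error of 0.33 (edgeR adjusted p = 0.000139, exact permutation p = 0.00794). Counts ran from 2225 to 7270 in control and from 147 to 261 in knockout libraries, so the knockout level was 3.96% of the control level and each library matched its genotype label.

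Genes known from inflammatory monocytes were among those that fell most in macrophages sorted from Ccr2 knockout mice, while C2, Vsig4 and Alox5 were among those that rose. Chil3, a chitinase-like protein made by monocytes and activated macrophages, fell from 372 ± 333 to 6.94 ± 5.86 CPM (log2 fold change -5.74, SE 0.76, adjusted p = 0.00540). Ly6c2, which encodes the surface antigen that marks inflammatory monocytes, fell from 85.2 ± 18.3 to 5.43 ± 3.32 CPM, and Plac8 fell from 94.5 ± 14.98 to 6.02 ± 3.998 CPM (n = 5 per group, edgeR adjusted p = 0.00353 and 0.00226). The coagulation factor genes F10 and F7 fell together, F10 from 65.3 ± 38.7 to 3.85 ± 2.44 CPM and F7 from 8.31 ± 5.77 to 0.889 ± 0.612 CPM. In the other direction C2, a protease of the complement cascade, rose from 1.26 ± 0.365 to 17.6 ± 13.4 CPM (log2 fold change 3.79, SE 0.59, adjusted p = 0.0135). With closely alike control libraries summed, C2 no longer passed (adjusted p = 0.144).

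**Figure D1:**
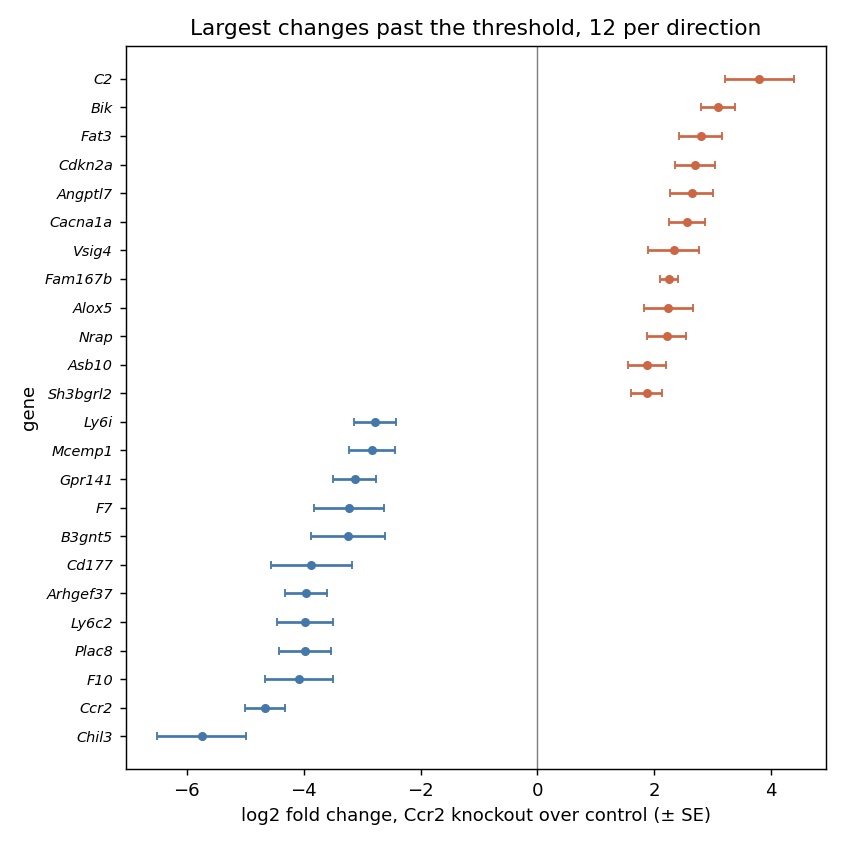
Log2 fold change of Ccr2 knockout over control macrophages with its standard error for the 12 genes with the largest change in each direction among those past the threshold with a mean of at least 2 CPM and no predicted-gene or pseudogene name, from 5 libraries per genotype. Chil3 lies lowest at -5.74 and C2 highest at 3.79.

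Of 14374 genes tested, 203 passed the threshold, 125 of them higher and 78 lower in Ccr2 knockout macrophages. The change was at least 2-fold for 61 of the higher and 65 of the lower genes. In 200 of the 203 the libraries of the groups did not overlap, which adds no support, since the same libraries picked these genes. The same held for 676 of all tested genes, or 4.70%. Chance gives 0.794% only if the libraries can be exchanged freely, which the close control pairs described below go against. Besides C2, the largest rises among genes with a mean of at least 2 CPM were those of Bik, a pro-apoptotic member of the Bcl2 family (log2 fold change 3.09), the protocadherin Fat3 (2.79), the cell cycle inhibitor Cdkn2a (2.70), Angptl7 (2.64) and the calcium channel subunit Cacna1a (2.55). Vsig4, a complement receptor of tissue-resident macrophages, rose from 8.78 ± 6.35 to 44.1 ± 18.8 CPM, and Alox5, the lipoxygenase that begins leukotriene synthesis, from 12.1 ± 4.41 to 57.2 ± 34.2 CPM. Fam167b (2.25), Nrap (2.21), Asb10 (1.88) and Sh3bgrl2 (1.87) completed the higher set. Among the lower genes were Arhgef37 (-3.96), the neutrophil glycoprotein gene Cd177 (-3.87), the glycosyltransferase gene B3gnt5 (-3.24), the orphan receptor gene Gpr141 (-3.13), Mcemp1 (-2.84) and Ly6i (-2.78), a relative of Ly6c2. Bik, Fam167b, Arhgef37 and 14 more of the 23 named genes other than Ccr2 passed the threshold with any single library left out. Alox5, Asb10, B3gnt5, Cd177, F7 and Vsig4 lost it in 5, 4, 9, 5, 4 and 6 of the 10 fits that left out 1 library, with adjusted p of up to 0.0903. Each of those 10 libraries ended at least 1 of these calls, control library 2 the most, with 6. Control libraries 1 and 2, and control libraries 3 and 4, were far closer to each other than other libraries of a group (median chi-square per gene 2.80 and 2.71, next 6.92, highest 24.1, sampling noise 0.455). Across groups, knockout library 2 was closer to control libraries 3 and 4 (5.96 and 6.88) than to any knockout library (7.22 or more). Counting each close control pair as 1 library left 29 of all genes past the threshold, and 12 of these 23. With knockout libraries 4 and 5 also summed, 8 of all genes and 3 of these 23 passed, and Chil3, Ly6c2 and Plac8 did not (adjusted p = 0.0806 for each). The count was 77, 62, 101 and 77 without control library 1, 2, 3 or 4, and 107 and 92 without knockout library 4 or 5. It was 50 without both of the latter, 800 with DESeq2 and 446 with limma-voom. Among 99 other splits of the libraries into 5 and 5, 98 gave 0 genes and 1, which crosses genotype, gave 603.

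Classical monocyte genes fell as a list and resident-like macrophage genes rose, while the core macrophage list did not pass. Of 19 classical monocyte genes tested, 7 fell over all genes and 11 adjusted over the list alone, and 18 had a negative log2 fold change (camera adjusted p = 4.28e-14, adjusted p = 0.0643 with an estimated correlation, fry adjusted p = 0.00112). Ccr2, the altered gene, is in this list and counts among the 7, the 11 and the 18. The list score, which includes Ccr2, was 5.91 ± 0.35 in control and 3.60 ± 0.58 in knockout macrophages (exact permutation p = 0.00794, adjusted p = 0.0460). Camera still called the list with Ccr2 left out. Of 24 resident-like genes, 5 rose over all genes and 10 adjusted over the list alone (camera adjusted p = 8.31e-07, adjusted p = 0.0643 with an estimated correlation, fry adjusted p = 0.00191). The 5 were Gas6, a ligand of receptors that take up dying cells (263 ± 49.3 to 584 ± 89.2 CPM), the growth factor Igf1 (48.2 ± 9.86 to 98.2 ± 15.05 CPM), the folate receptor Folr2 (135 ± 38.3 to 283 ± 61.4 CPM), Cbr2 (191 ± 32.1 to 458 ± 204 CPM) and Vsig4. The resident-like score was 4.83 ± 0.21 and 5.58 ± 0.11. The core macrophage list, which holds Csf1r, Adgre1 and the C1q genes, did not pass (camera adjusted p = 0.995, scores 9.87 ± 0.07 and 9.81 ± 0.06), although 1 of its 18 genes, the lysosomal glycoprotein gene Cd68, rose from 829.9 ± 49.4 to 1169 ± 115 CPM. Adjusted over the list alone, 1 was higher and 1 lower, the latter Lst1 at 144.95 ± 10.2 and 82.7 ± 23.8 CPM (adjusted p = 0.0785 over all genes). Each of control libraries 1 to 4 was needed for the calls of Folr2, Cbr2 and Cd68. Folr2 also needed knockout libraries 4 and 5, and Cbr2 control library 5 and knockout libraries 1, 4 and 5 (adjusted p without one of them up to 0.0866, 0.111 and 0.0832). With the close control pairs summed, none of the 5 resident-like genes passed (adjusted p = 0.0909 for Gas6, 0.114 for Igf1, 0.231 for Folr2, 0.264 for Cbr2 and 0.238 for Vsig4), nor did Cd68 (0.240). T and NK cell, neutrophil, fibroblast and dendritic cell markers also stood lower in the knockout libraries, with list score differences of -2.26, -2.41, -0.88 and -0.66 (exact permutation p = 0.0556, 0.0556, 0.103 and 0.0635, adjusted p = 0.165, 0.165, 0.192 and 0.165).

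**Figure D2:**
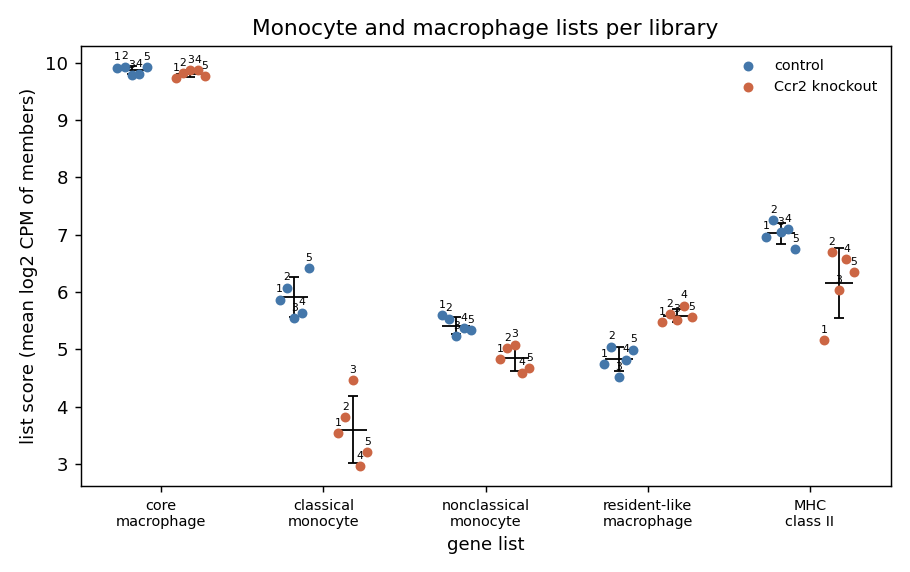
List scores, the mean log2 CPM of the tested members of each list, in each control and Ccr2 knockout library, with library numbers beside the points and the mean and SD as black lines. The classical monocyte score averaged 5.91 in control and 3.60 in knockout libraries, the core macrophage score 9.87 and 9.81.

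Nonclassical monocyte genes and chemokine receptor genes fell as lists, with few single genes past the threshold. Of 14 nonclassical monocyte genes, 0 fell over all genes and 5 adjusted over the list alone (camera adjusted p = 0.0106, adjusted p = 0.102 with an estimated correlation, fry adjusted p = 0.0131). Gngt2 had a log2 fold change of -0.59 and Adgre4, an adhesion receptor, of -1.45 (adjusted p = 0.0785 and 0.0888 over all genes). Of 14 chemokine receptor genes, 1 fell, Ccr2 itself, and 2 adjusted over the list alone (camera adjusted p = 8.51e-05, adjusted p = 0.0643 with an estimated correlation, fry adjusted p = 0.00132). Of the chemokine receptor genes 6 of 14 are in another list, and T and NK cell, neutrophil and dendritic cell scores differed by -2.26, -2.41 and -0.66 in the same libraries. With Ccr2 left out of every list, 9 of the lists of pathways and cell states were still called.

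MHC class II, type I interferon and inflammatory genes fell as lists by camera, although 0 of their members passed the threshold over all genes. The MHC class II list had 4 of 16 genes lower adjusted over the list alone (camera adjusted p = 9.03e-05, adjusted p = 0.622 with an estimated correlation). H2-Ab1 stood at 1950.4 ± 426 CPM in control and 708 ± 440.4 CPM in knockout libraries, and H2-Aa at 1895 ± 450.2 and 628 ± 431 CPM. Knockout library 1 had the lowest class II score at 5.16. The class II score differed between the genotypes (exact permutation p = 0.00794, adjusted p = 0.0460), while fry did not call the list (adjusted p = 0.143). Dendritic cell markers fell as a list in the same libraries, with a score difference of -0.66 (camera adjusted p = 0.00411, adjusted p = 0.447 with an estimated correlation). Of 29 type I interferon genes, 28 had negative log2 fold changes and 0 passed adjusted over the list alone (camera adjusted p = 5.03e-07, adjusted p = 0.685 with an estimated correlation). Ifi204 had a log2 fold change of -0.73 and Oas2 of -0.71. The type I interferon score did not differ past the threshold (exact permutation p = 0.111, adjusted p = 0.276). Knockout libraries 2 and 5, at 6.75 and 6.51, lay within the control range of 5.96 to 6.99, while knockout libraries 1 and 3 stood at 4.62 and 5.17. Of 28 inflammatory genes, 0 passed adjusted over the list alone, with Il1b, the gene of interleukin-1 beta, at 1101 ± 458 and 343 ± 271 CPM (camera adjusted p = 0.000854, adjusted p = 0.685 with an estimated correlation). Knockout libraries 4 and 5 had inflammatory scores of 4.34 and 4.56 against 6.10 to 6.46 in the other knockout libraries, and the call ended without both of them (adjusted p = 0.872). The inflammatory score did not differ past the threshold (exact permutation p = 0.143, adjusted p = 0.276). Early-response genes, which include Junb and Btg2, had scores of 8.81 ± 0.24 in control and 7.86 ± 0.88 in knockout libraries.

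Proliferation and cholesterol synthesis genes rose as lists by camera, with 0 members past the threshold over all genes. Of 34 proliferation genes 33 had positive log2 fold changes and 0 passed adjusted over the list alone (camera adjusted p = 4.16e-07, adjusted p = 0.685 with an estimated correlation). The cyclin-dependent kinase gene Cdk1 stood at 44.6 ± 13.8 CPM in control and 70.9 ± 13.4 CPM in knockout libraries, and the helicase gene Mcm6 at 123 ± 33.4 and 180.3 ± 31.6 CPM. The proliferation score was 5.31 ± 0.60 in control and 5.77 ± 0.25 in knockout libraries (exact permutation p = 0.143). Control library 5 had the lowest score at 4.39, control libraries 3 and 4, at 5.97 and 5.67, lay within the knockout range of 5.49 to 6.04, and the list still passed camera without control library 5. Of 24 cholesterol synthesis genes, 2 passed adjusted over the list alone, Dhcr7 with a log2 fold change of 0.48 and Lss with 0.60 (camera adjusted p = 0.0484, adjusted p = 0.793 with an estimated correlation). The cholesterol call ended without control library 3, 4 or 5 or knockout library 1 or 3, with adjusted p of 0.0726, 0.0870, 0.0584, 0.137 and 0.431. It also ended with limma-voom (0.171) and with a filter of at least 1 CPM in 5 libraries (0.0611).

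In total, 9 of the 29 lists of pathways and cell states passed camera, 6 lower and 3 higher, of which 0 held with an estimated correlation and 4 held by fry. Among 100 ways of splitting the 10 libraries into 5 and 5, the real one included, 55 called at least 9 lists. The other 20 lists had camera adjusted p from 0.0531 to 0.995: lysosome and phagocytosis, interferon gamma, myeloid transcription factors, MHC class I, iron and haem, oxidative phosphorylation, Nrf2, unfolded protein and integrated stress, MAPK feedback targets, lipid-associated macrophage, glycolysis, immune checkpoint and suppression, chemokine ligands, complement, alternative activation, growth factors, lipid efflux, matrix remodelling, core macrophage and hypoxia. Median, mean and test differed in sign in 6 of the 42 lists tested, none of them called, which were core macrophage, hypoxia, lipid efflux, B and plasma cell, eosinophil, and mast cell and basophil.

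Markers of T and NK cells, neutrophils, fibroblasts and dendritic cells stood lower in Ccr2 knockout libraries, while B and plasma cell markers did not pass. The T and NK cell list fell (camera adjusted p = 1.02e-08, adjusted p = 0.447 with an estimated correlation), with 0 of 21 genes past the threshold and 0 adjusted over the list alone. Its regulatory T cell gene Foxp3 stood at 2.26 ± 1.35 and 0.590 ± 0.366 CPM. The neutrophil list fell (camera adjusted p = 2.80e-06, adjusted p = 0.447 with an estimated correlation), with 0 of 16 genes past the threshold and 6 adjusted over the list alone, among them Csf3r at 162 ± 15.3 and 110.4 ± 22.1 CPM and the granule gene Ltf at 8.35 ± 9.99 and 0.586 ± 0.674 CPM. Fibroblast genes fell as a list with 0 of 20 past the threshold and 2 adjusted over the list alone, Mfap5 and Col5a2 (camera adjusted p = 0.000125, adjusted p = 0.513 with an estimated correlation). Dendritic cell genes fell with 1 of 23 past the threshold, Dpp4, from 4.55 ± 1.79 to 0.918 ± 0.453 CPM, and 1 adjusted over the list alone (camera adjusted p = 0.00411, adjusted p = 0.447 with an estimated correlation). All of these lists were still called by camera without knockout libraries 4 and 5 together, as was the early-response list. Dpp4 lost the threshold without control library 1, 2, 3 or 4 or knockout library 4 or 5, with adjusted p of up to 0.0838, and with the close control pairs summed (0.171). Early-response genes (22 tested) and mitochondrially encoded genes (7 tested) also fell as lists, with 0 past the threshold and 0 and 2 adjusted over the list alone (camera adjusted p = 1.02e-07 and 0.00411, adjusted p = 0.447 for both with an estimated correlation).

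**Figure D3:**
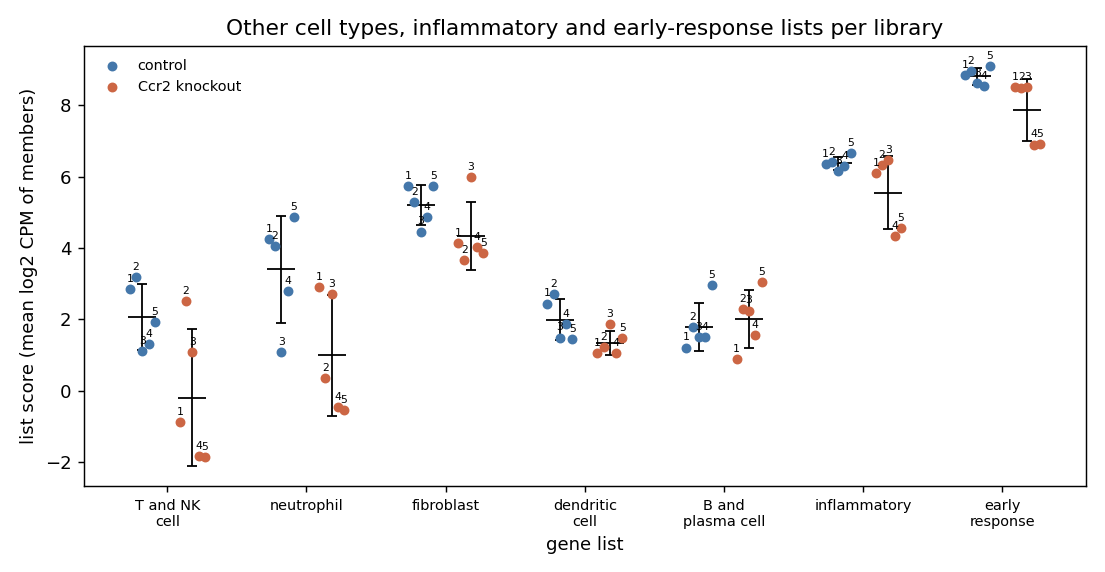
List scores in mean log2 CPM for markers of other cell types, inflammatory genes and early-response genes in each library, numbered, with the group mean and SD as black lines. Knockout libraries 4 and 5 have early-response scores of 6.90 and 6.91, while the control libraries lie between 8.53 and 9.10.

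The remaining 7 of these 13 lists had camera adjusted p from 0.0658 to 0.992 and held endothelial, pericyte and smooth muscle, eosinophil, keratinocyte, B and plasma cell, mast cell and basophil, and melanoma genes. All 6 calls were lost both with an estimated correlation and by fry, and 25 of the 100 splits of the libraries called at least 6 lists. Among the genes of the 7 lists not called, 1 pericyte and smooth muscle gene fell, Tagln, with a log2 fold change of -2.32 that turned to 0.46 with unstranded counts, and 1 melanoma gene rose, Trpm1, with 1.96 (edgeR adjusted p = 0.0372 and 0.0270). Tagln lost the threshold without any library but control 3 and knockout 3 (adjusted p up to 0.103), and Trpm1 without control library 1, 2, 3 or 4 or knockout library 4 (up to 0.0782), and both lost it with the close control pairs summed (0.151 and 0.167). Melanoma genes, which report tumour cells, had scores of 2.30 ± 0.79 in control and 2.12 ± 0.22 in knockout libraries. Of the 11 tested, 9 had negative log2 fold changes, unlike Trpm1.

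Measures of reads and counts per library did not differ between the genotypes past the threshold. Genes took 85.8 ± 0.806% of reads in control and 86.1 ± 1.16% in knockout libraries, and mitochondrially encoded genes took 0.716 ± 0.134% and 0.596 ± 0.136% of counts (exact permutation p = 0.579 and 0.190). The 50 most abundant genes took 20.2 ± 0.654% and 20.03 ± 1.31% of counts. Of 7 such measures, 0 passed after adjustment, with the lowest adjusted p at 0.824. This does not show equal quality, since lists of technical signs did differ. Early-response scores reached at most 8.51 in knockout and at least 8.53 in control libraries (exact permutation p = 0.00794, adjusted p = 0.103). Mitochondrially encoded genes fell as a list by camera (adjusted p = 0.00411, adjusted p = 0.447 with an estimated correlation).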

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

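The tests of explanations below were chosen after the results were seen, except the counts over other splits of the libraries.

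Control library 5 stood apart from the other control libraries in 3 of the 24 named genes, with log2 CPM of 9.92 for Chil3 (others 7.50 to 7.99), 4.33 for Vsig4 (2.48 to 2.79) and -1.19 for Cdkn2a (-0.20 to 0.19). Control library 1 stood apart for C2 at -0.49 (0.43 to 0.77), and knockout library 3 for the fibroblast score at 5.99 (3.66 to 4.13). Chance marks about 1 group in 20, or 7.4 of the 148 groups looked at, and 5 were marked.

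The first pattern is the fall of classical monocyte genes with the rise of resident-like genes. Of the 29 tested neighbours of Ccr2, 0 belong to these lists, and the 11 other members past the threshold lie on other chromosomes. A direct effect of the altered allele on genes beside it would therefore not reach these lists. That follows from where the genes lie and not from their levels. Whether the allele changes its neighbours was not settled. Of the 29, 0 passed, but only 1.41% of all genes did, so few were due. At an unadjusted p under 0.05 in edgeR the shares were 13.8% of neighbours and 15.3% of all genes. Depth is argued against, with a ratio of mean total counts of 1.02. A lower share of monocyte-stage cells among the sorted macrophages cannot be told apart from less monocyte RNA per cell: the monocyte score fell further than the core macrophage score, by a difference of -2.25 (exact permutation p = 0.00794), but this restates the pattern and decides nothing. A genotype effect stays open.

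The second pattern is the fall of T and NK cell, neutrophil, fibroblast and dendritic cell markers. Of their tested members, 0 of 21, 4 of 16, 0 of 20 and 7 of 23 are also in another list, and abundant ones such as Il2rb (14.8 CPM in control, 7.67 in knockout), S100a9 (65.4 and 18.3), Col3a1 (808 and 675) and Wdfy4 (167 and 184) were measured in a sort for F4/80 that should remove lymphocytes, neutrophils and fibroblasts. Less carry-over of every other cell type alike cannot be told apart from separate changes: the changes of the 11 lists ran from -2.41 to 0.22 with an SD of 0.86 (exact permutation p = 0.0714). Whether knockout libraries 4 and 5 alone carry it cannot be told apart either: without them 61.3% of the mean change was left (51.5, 58.7, 70.3 and 92.7% in the order above) and camera still called all of these lists, but exact permutation p lay between 0.179 and 0.339. A genotype effect on these cells in the tumours stays untested.

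The third pattern is the fall of early-response and inflammatory genes. For inflammatory genes the difference may rest on knockout libraries 4 and 5, since 10.2% of it was left without them (exact permutation p = 0.571). For early-response genes 32.4% was left (exact permutation p = 0.0536) while camera still called the list, so whether these libraries alone carry it stays open. A difference in handling before or during the sort cannot be told apart from genotype, because the labels give no sort day, and the early-response score differed by -0.95 (exact permutation p = 0.00794, adjusted p = 0.103). A genotype effect stays open too.

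Other splits of the libraries bear on the counts. Of 100 splits drawn from 126, 2 gave at least 203 genes, the real one and 1 with 603. That share lies under 0.05, but it counts against chance only if the libraries can be exchanged freely. The close control pairs go against free exchange, and with those pairs summed 29 genes passed. The split with 603 genes set control libraries 1, 2 and 5 with knockout libraries 1 and 3 against the rest, while each of the other 98 gave 0, which points to a structure of the samples that crosses genotype and that the labels do not name. For lists of pathways and cell states, 55 splits gave at least 9 and the highest other split gave 18, and for other cell types 25 gave at least 6 and the highest gave 9, so chance is not excluded for either count of lists.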

How the results depend on the processing

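The fits with summed libraries, without knockout libraries 4 and 5 together, and with Ccr2 left out of every list were chosen after seeing the data. All 203 genes kept their direction under each alternative for single genes except at least 1 CPM in 5 libraries, where 194 matched, and unstranded counts, where 200 did; genes no longer tested count as not matched. The 203 calls became 800 with DESeq2 (51.5% higher), 446 with limma-voom, 126 with a fold of at least 2 and 444 at an adjusted p of 0.1, and 62 (without control library 2) to 267 (without knockout library 3) with 1 library left out. They became 29 with the 2 control pairs summed, 8 with knockout libraries 4 and 5 summed as well, and 50 without those 2, where fewer samples entered; the cause of the other shifts was not tested. DESeq2 size factors gave 199, no composition factor 205, no filter 175, the stricter filter 193, unstranded counts 207 and robust dispersions 198. Title numbers do not pair the samples: same-numbered libraries correlated in their deviations between -0.529 and 0.344, and not every sample correlated best with its own number. With the number as a replicate block 55 genes were called, with 11 lists of pathways and 6 of other cell types. Lists of pathways and cell states moved from 9 to 14 with no composition factor, 0 with an estimated correlation and 4 by fry, and ran from 9 to 13 with 1 library left out. The 6 other lists became 0 with an estimated correlation and 0 by fry, and ran from 6 to 8. Ccr2 ran from -4.83 to -4.47 with 1 library left out and stayed past the threshold throughout; library measures gave 0 calls in every setting run. Of 84 single genes followed, Tagln, a smooth muscle gene lower by edgeR, reversed with unstranded counts, to a log2 fold change of 0.46. That column also counts reads of the opposite strand, but the cause of the reversal was not tested. The deposited combined table was not run, for want of column names, and robust dispersions give no list result since camera does not use them. At this depth and spread 12.7% of genes changed 1.5-fold were recovered in simulation, which did not vary depth.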

Other observations

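The test of neighbouring genes and the values per library below were chosen after the results were seen.

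Single genes of lists that did not pass as lists also changed. Among 26 growth factor genes 3 rose and 0 fell, also 3 adjusted over the list alone. They were Igf1, Vegfb, from 19.6 ± 1.05 to 28.8 ± 2.60 CPM, and the platelet-derived growth factor gene Pdgfc, from 43.6 ± 9.17 to 71.9 ± 3.66 CPM (edgeR adjusted p = 0.0168 and 0.0260 for the last pair). Vegfb lost the threshold without control library 1, 2 or 4 (adjusted p up to 0.0567), and Pdgfc without control library 1, 2, 3 or 4 or knockout library 4 or 5 (up to 0.0790). Of 27 matrix remodelling genes 1 rose, the metalloproteinase inhibitor gene Timp2, from 737 ± 189.8 to 1345 ± 247 CPM, and 2 were higher and 2 lower adjusted over the list alone. Timp2 lost the threshold without any library but control 5 and knockout 2 (adjusted p up to 0.118). With the close control pairs summed, Vegfb, Pdgfc and Timp2 did not pass (adjusted p = 0.151, 0.177 and 0.284). In the alternative activation list 1 of 21 genes fell, Chil3. Of 19 complement genes 2 rose, C2 and Vsig4. Of the Nrf2 list 4 of 19 genes and of the iron and haem list 2 of 16 were higher adjusted over the list alone, with 0 past the threshold over all genes.

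The MAPK feedback list, which holds Dusp and Spry genes that report ERK signalling, had scores of 5.46, 5.26, 4.05, 4.27 and 4.86 in control libraries 1 to 5 and 5.22, 4.17, 5.33, 3.30 and 3.39 in knockout libraries 1 to 5 (camera adjusted p = 0.179 between genotypes). Scores of 4.86 or more were those of control libraries 1, 2 and 5 and knockout libraries 1 and 3, the same libraries that stand on one side of the split with 603 genes, which was seen afterwards and not tested. The growth factor list also divided there, with its lowest score on that side at 3.76 and its highest on the other at 3.56. Lists of other kinds did so too, by narrower or wider gaps. Matrix remodelling had 6.46 against 6.45, iron and haem 6.32 against 6.29, mast cell and basophil 0.40 against 0.12, and keratinocyte -0.48 against -0.64. MHC class I and interferon gamma divided there in the other direction. Their highest scores on that side were 7.91 and 5.15, and their lowest on the other 8.15 and 5.30. The split is therefore not particular to signalling genes. The spread of MAPK feedback scores within each genotype exceeded the difference between their means, 4.78 and 4.28. The first principal component held 36.1% of the variance (exact permutation p = 0.0476 between genotypes) and the second 18.1% (p = 0.127). On the first component the genotypes overlapped, at -56.4 to 12.8 in control and -25.4 to 63.6 in knockout libraries. The sides of the split with 603 genes overlapped less, at -56.4 to 5.79 and -3.23 to 63.6. The first component is thus not an axis of genotype alone.

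Xist, the transcript that silences an X chromosome in female cells, was counted at 6.94 to 25.2 CPM in these libraries from mice labelled male, alongside the Y-linked genes Ddx3y at 28.1 to 50.3 CPM and Uty at 7.83 to 15.2 CPM. Neither Xist nor these Y-linked genes differed past the threshold (edgeR adjusted p = 0.526, 0.599 and 0.556).

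A hypothesis is that genes beside each other share a linked cause. In GRCm38 order, 9 adjacent tested pairs passed the threshold in 1 direction, against a mean of 1.48 in 10000 random draws of genes (permutation p = 1e-04, the smallest these draws can give). F7 with F10, Ly6c2 and the melanoma list gene Trpm1 are in such pairs, and what links the genes of a pair was not tested.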
